A study of Salmo salar with 16 samples.

How the data were processed

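Liver RNA of 16 Atlantic salmon samples was measured on single-colour Agilent arrays, 4 samples in each of 4 groups (0, 15, 70 and 280 mGy). Per the labels' protocols, total RNA was taken from 20 to 30 mg of snap-frozen liver with an RNA integrity number above 8.0, and 200 ng was labelled with Cy3. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 10.7. The deposited scanner files hold, per spot, the processed signal, the median signal and the median local background as intensity on a linear scale, with no normalization between arrays. Other columns used were the software's flags for outlier spots, saturation and signal well above background, per the file headers. The authors also deposited a table of 45380 probes for the 16 arrays, whose scale is not given in the sources used here. Read from the values, the authors deposited log2 signal after quantile normalization: the match with the scanner files had r from 0.999 to 1.00 and slopes from 0.993 to 1.00, and each probe was centred on its median over the 16 arrays (all 45380 row medians were 0 within 1e-06). The medians of its columns lay between -0.0401 and 0.0208.

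The main values were log2 of the processed signal minus each array's 75th percentile. The 1319 control spots among 62976 were left out and flagged outlier spots were set to missing. Spots of 1 probe were averaged on the log2 scale: 49679 probes had 1 spot, 5739 had 2 and 50 had 10. Probes well above background on all 4 arrays of at least 1 group were kept, 31631 of 55468. Low signals are the least certain, and a probe not well above background on any array of a group has only a bound there. Scaling by 1 percentile per array removes a shift common to all probes, so differences are relative to the array as a whole.

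Linear models with empirical Bayes variances were fitted in limma 3.58.1 (R 4.3.3) on all 16 arrays with 4 group means. Contrasts were each dose against control, a trend over the order of the doses, and the doses against each other. P-values were two-sided and adjusted per contrast by the Benjamini-Hochberg method with a threshold of 0.05. The design, the filter and the alternatives were fixed before the data were examined, apart from those said to be added later. Array measures were compared by exact permutation tests of the group means.

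The fits were tested on simulated data of 280 mGy against control, with 31512 probes, 4 arrays per group and 200 changed probes in each of 10 runs. They recovered 23.4% of probes changed 2-fold, 72.2% at 4-fold, 90.8% at 8-fold and 97.4% at 16-fold, with 65 false calls over all runs, and 5.06% of unchanged data fell under an unadjusted p of 0.05.

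Gene names were sought by matching the target identifiers to every identifier column of a table of 65341 RefSeq genes of the species, without versions. As 0 matched and the files pair the identifiers with no symbol, the gene lists, the cell type markers and the rule for named genes that had been fixed beforehand could not be applied. The 4 probes named by identifier are the 2 higher and the 2 lower probes with the smallest unadjusted p at 280 mGy, a choice made after the values were seen.

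Alternatives were quantile normalization, scaling by the median, normexp background correction (offset 50) with either scaling, the authors' table, no filter, a filter on all 16 arrays (21689 probes), an intensity-dependent and robust variance prior, array quality weights, fits of only the 2 groups compared, the replicate number or the slide as a block, each array left out, other thresholds, analysis of variance and a trend over the dose in mGy. The files used here hold no mean signal, so normexp was run on the median signal, unlike the plan. Added after seeing the data were fits without 70 mGy replicate 1 and with slide as a block, with outer or inner position as a covariate, within each slide, and of 2 groups with slide as a block. Scan time divided the arrays as the slides did, so slide stands for both. Counts were also recomputed for all 35 splits of the 8 arrays of each dose and control, for 100 orders of the 16 arrays for the trend, and for 100 orders that kept each array on its slide, added after the others were seen. No 2 arrays were near duplicates: the highest correlation between arrays was 0.983, for control replicate 1 and 280 mGy replicate 1. The highest within a group was 0.968.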

Results

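Gene expression was measured in the liver of juvenile Atlantic salmon (Salmo salar, at the freshwater parr stage) after external gamma irradiation from a cobalt-60 source. The 16 liver RNA samples fell into 4 groups of 4: unexposed controls, and total doses of 15, 70 and 280 mGy given over 48 h in the dark, after 72 h in the exposure water without food. The question stated in the title of the series was whether the liver transcriptome responds to sublethal doses in a dose-dependent way. Each sample was hybridised to 1 single-colour Agilent array, so the comparisons below are 4 arrays against 4, and their number limits the precision. The labels speak of fish livers and number the samples within a group but do not state that each came from a separate animal, so p-values measure the spread between these samples.

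Each array held 55468 probes other than controls. Between 51.3% (70 mGy replicate 1) and 70.9% (15 mGy replicate 1) of them were well above background, and 31631 were so on all 4 arrays of at least 1 group and entered the tests. No spot was saturated on any array. The mean share of probes well above background was 60.9% ± 3.31 in controls, 61.4% ± 7.10 at 15 mGy, 54.6% ± 3.81 at 70 mGy and 59.0% ± 5.27 at 280 mGy (SD, n = 4 each). The 75th percentile of the signal, by which each array was scaled, was 208 ± 39.1 scanner units at 70 mGy and 291 ± 6.48 in controls (SD, n = 4 each). That difference gave p = 0.0286 in a two-sided exact permutation test, the smallest p that 4 arrays against 4 can give, and 0.114 after Benjamini-Hochberg adjustment over the 8 array comparisons made. The arrays lay on 2 slides that each held 2 arrays of every group. The share of probes well above background was 62.1% on slide 1 and 55.9% on slide 2, with an exact permutation p of 0.0143 and an adjusted value of 0.114.

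**Figure D1:**
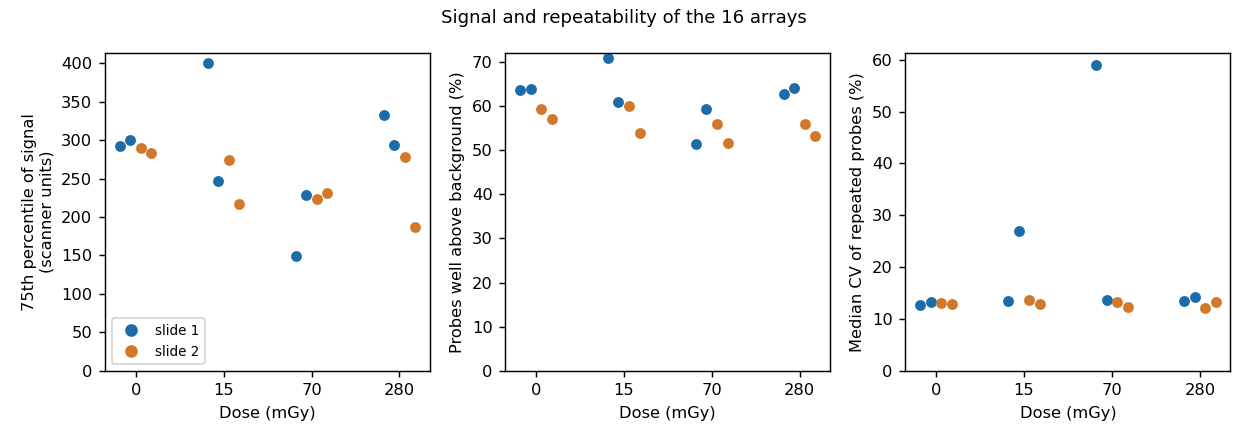
Array quality by dose (x axis, mGy), 1 point per array, coloured by slide: the 75th percentile of the signal in scanner units, the percentage of probes well above background, and the median coefficient of variation (CV, %) of probes printed on several spots. The CV was 58.9% on 70 mGy replicate 1 and 27.0% on 15 mGy replicate 2, and the 75th percentile was lowest, at 149.7, on 70 mGy replicate 1.

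The probes carry identifiers of the array design, and the files do not pair these with gene names: 0 of the 55468 probes matched any column of a table of 65341 RefSeq genes of this species. The results are therefore given per probe, and 4 probes are named by their identifiers, 2 higher and 2 lower at 280 mGy with the smallest p in each direction, chosen after their values were seen. Whether genes of DNA repair, oxidative stress or any other process changed was not analysed here.

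The comparison of 280 mGy with control asked which transcripts responded to the highest dose. Signal of probe CUST_15910_PI426552878 was -1.61 ± 0.26 in controls and 0.73 ± 0.47 at 280 mGy on the log2 scale relative to each array's 75th percentile (SD, n = 4 each), a difference of 2.34 ± 0.463 (SE) or 5.07-fold, and all 4 irradiated samples lay above all 4 controls. Probe CUST_47380_PI426552878 was 2.52-fold higher, with a log2 difference of 1.33 ± 0.253 (SE), again without overlap between the 4 irradiated and the 4 control samples. Probe CUST_11929_PI426552878 was lower, from 0.40 ± 0.36 in controls to -0.94 ± 0.31 at 280 mGy (SD, n = 4 each), a log2 difference of -1.34 ± 0.232 (SE). Probe CUST_22230_PI426552878 was well above background on all 4 control arrays, with log2 signals from -2.94 to -0.23, and on 0 of 4 arrays at 280 mGy. This gives an approximate bound of 3.75-fold lower signal, which is not a firm minimum. That bound sets the mean of the control arrays against the mean, over the arrays at 280 mGy, of the higher of the probe's own signal and the lowest signal of any probe well above background. With normexp background correction the fitted log2 difference of this probe was -1.06, and -1.12 with quantile normalization in addition, both smaller in size than the bound and than the -3.22 fitted to the processed signal. That of CUST_15910_PI426552878 was 1.64 and 1.58 in these settings. Each of these 4 differences had an adjusted p of 0.34 in limma, so none passed the threshold of 0.05. The 4 probes were chosen by this same comparison, so the size of their differences and the lack of overlap are partly fixed by that choice.

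At 280 mGy 0 of the 31631 probes passed an adjusted p of 0.05 in the limma fit of all 4 groups, and the lowest adjusted p was 0.34. At an unadjusted p under 0.05 there were 3230 probes, or 10.2%, where 1582 were expected by chance, with 1601 higher and 1629 lower than in controls. The share higher was 49.6% and ranged from 42% to 53.8% over the alternatives run. Among them 435 were at least 2-fold higher and 564 at least 2-fold lower. At an unadjusted p under 0.001 there were 88 probes, with 31.6 expected. The 4 irradiated and 4 control samples did not overlap for 6.75% of all probes (1122 higher and 1014 lower), and chance gives 2.86%. Most probes differed little: 81.4% lay within 1.5-fold of control, while the median 95% confidence interval of a log2 difference reached 0.656 to either side. In data simulated for this comparison, 23.4% of probes given a 2-fold change and 72.2% of those given a 4-fold change passed the adjusted threshold. These rates hold for noise independent between probes and 200 changed probes of 31512, and may differ for the real arrays.

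With only the control and 280 mGy arrays in the limma fit, 6 probes passed the adjusted threshold, 1 higher and 5 lower, with a lowest adjusted p of 0.000368. The higher probe was CUST_15910_PI426552878, with an adjusted p of 0.0493 in that fit. With slide as a block in addition 2 probes passed, and the adjusted p of CUST_15910_PI426552878 was 0.084. Within slide 1 the count at an unadjusted p under 0.05 was 658 and within slide 2 it was 4841, with 0 adjusted calls on either. With slide as a block it was 3836, again with 0 adjusted calls. All 4 control arrays were in inner columns of their slides and all 4 arrays at 280 mGy in outer columns. With position on the slide as a covariate the count was 2733, against 3230 without it, with 0 adjusted calls. Of these 2733 probes, 1163 were higher and 1570 lower (42.6% higher). That fit could estimate position only within the lower doses, so it does not separate position from dose at 280 mGy. Without control replicate 4 the count was 1889 in the fit of all groups.

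**Figure D2:**
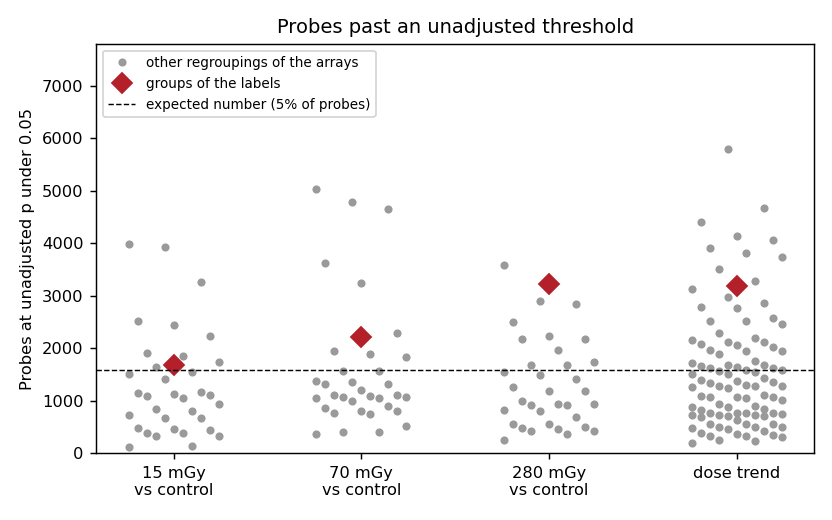
Number of probes at an unadjusted p under 0.05 (y axis) for each dose against control and for the trend over the doses (x axis). The diamond is the grouping of the labels (1679, 2210, 3230 and 3196 probes), each grey point is another regrouping of the same arrays, and the dashed line is the 1582 probes expected by chance. Other regroupings reached 3995, 5031, 3580 and 5797 probes.

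At 70 mGy the same 2 higher probes had log2 differences from control of 1.68 ± 0.463 (SE) for CUST_15910_PI426552878 and 0.86 ± 0.253 (SE) for CUST_47380_PI426552878. CUST_11929_PI426552878 differed by -0.91 ± 0.232 (SE). CUST_22230_PI426552878 differed by -1.52 ± 0.55 (SE) and was well above background on 1 of 4 arrays at this dose. Each of these had an adjusted p of 0.697 in limma. The probes were chosen by their difference from the same control arrays at the highest dose. Differences in the same direction here are therefore partly fixed by that choice and are no independent result. Over all probes 0 passed the adjusted threshold, and 2210 (6.99%) had an unadjusted p under 0.05, with 1223 higher and 987 lower than control. The share higher among these was 55.3%, and its direction depended on the setting: it was 65.6% with arrays scaled by their median and 69.1% with normexp background correction, but 37.5% within slide 2 and 42.6% with position on the slide as a covariate. Without 70 mGy replicate 1 it was 39.8% (582 higher and 881 lower), and 34.7% with slide as a block in addition. The 4 exposed and 4 control samples did not overlap for 3.83% of probes, against 2.86% by chance. The unadjusted count was 754 within slide 1, 2437 within slide 2 and 2758 with slide as a block. It was 1463 without 70 mGy replicate 1, the array with the noisiest repeated spots, 4020 without 70 mGy replicate 4 and 1021 without control replicate 4.

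At 15 mGy CUST_15910_PI426552878 differed from control by 1.33 ± 0.463 (SE) on the log2 scale and CUST_47380_PI426552878 by 0.94 ± 0.253 (SE). CUST_11929_PI426552878 differed by -0.41 ± 0.232 (SE), and CUST_22230_PI426552878 by -1.92 ± 0.55 (SE) with 3 of 4 arrays well above background. Each had an adjusted p of 0.833 in limma. Here too the control arrays were those used to choose the probes, so the direction of these differences is partly fixed by that choice. Over all probes 0 passed the adjusted threshold, and 1679 (5.31%) had an unadjusted p under 0.05, close to the 1582 expected, with 973 higher and 706 lower. The share higher, 58%, also turned with single arrays: it was 44.6% (266 higher and 330 lower) without control replicate 4, 46.8% without 15 mGy replicate 4, 47.9% without 15 mGy replicate 2 and 49% without 15 mGy replicate 1, but 68.7% without control replicate 1. Within slide 1 it was 43%. The 2 groups did not overlap for 3.15% of probes. The unadjusted count was 370 within slide 1, 3226 within slide 2 and 2311 with slide as a block. Leaving out 1 array took it from 596, without control replicate 4, to 2746, without control replicate 1.

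**Figure D3:**
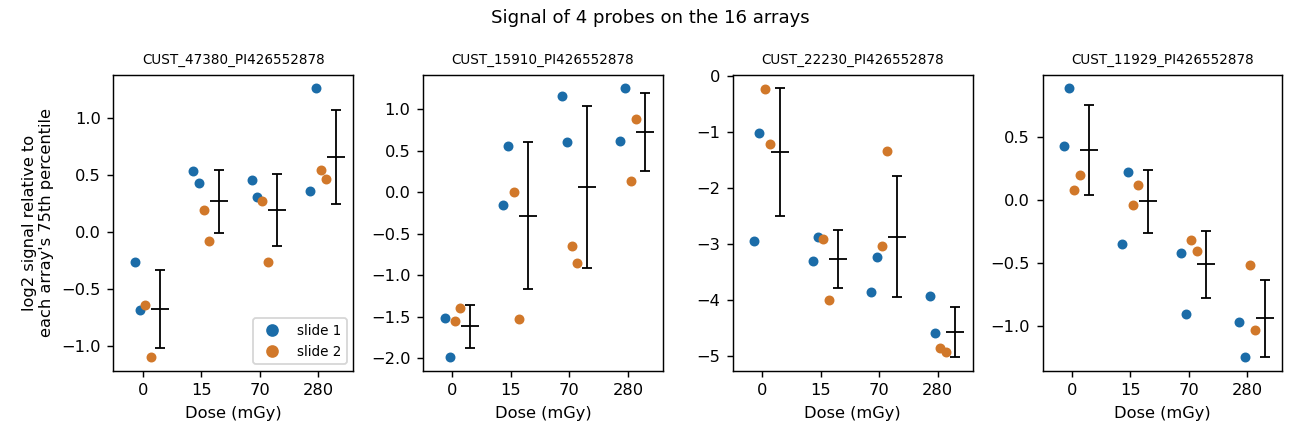
Log2 signal relative to each array's 75th percentile (y axis) of the 4 named probes by dose (x axis, mGy), 1 point per array coloured by slide, with the mean and SD of the 4 arrays beside them in black. CUST_15910_PI426552878 went from -1.61 in controls to 0.73 at 280 mGy, and CUST_22230_PI426552878 was not well above background on any array at 280 mGy.

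The trend over the 4 dose levels asked which transcripts followed the dose. CUST_15910_PI426552878 was higher by 0.74 ± 0.147 log2 units (SE) per dose level and CUST_47380_PI426552878 by 0.39 ± 0.0799 (SE), both with an adjusted p of 0.29 in limma. CUST_11929_PI426552878 had a slope of -0.45 ± 0.0734 (SE) per level, with an adjusted p of 0.258, the lowest of all probes. The named probes were chosen by their difference between the highest dose and control, which weighs most in this trend. Their slopes are therefore partly fixed by that choice. Over all probes 0 passed the adjusted threshold and 3196 (10.1%) had an unadjusted p under 0.05, with 1570 slopes upwards and 1626 downwards. A trend over the dose in mGy, which weights the highest dose more, gave 0 adjusted calls and 2288 probes at an unadjusted p under 0.05, with 911 slopes upwards and 1377 downwards (39.8% upwards). The unadjusted count was 727 within slide 1, 4357 within slide 2, 3782 with slide as a block and 2011 without control replicate 4. Position on the slide also followed the dose. All control arrays lay in inner columns and all arrays at the highest dose in outer columns. The doses between had both, with more outer arrays at the higher of them. With position as a covariate the count was 2587, with 0 adjusted calls. That fit could estimate position only within the doses between, so it does not separate position from dose in the trend. Of the 31512 probes measured on all arrays, the 4 group means increased at each dose step for 1995 and decreased at each step for 1958, together 12.5% against 8.33% by chance. In a one-sided permutation test over 1000 orders of the 16 arrays, chosen after the counts were seen, this had p = 0.093, and p = 0.1 over 1000 orders that kept each array on its slide.

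Between the irradiated groups 0 probes passed the adjusted threshold in limma in any of the 3 comparisons. The probes at an unadjusted p under 0.05 numbered 944 for 70 against 15 mGy, 1276 for 280 against 15 mGy and 963 for 280 against 70 mGy, each below the 1582 expected by chance. This side of 1582 depended on the setting. With array weights the counts for 70 and for 280 against 15 mGy were 2357 and 2765, with position on the slide as a covariate those for 280 against 15 and against 70 mGy were 2370 and 1842, and within slide 2 the 3 counts were 1769, 2116 and 1777. With slide as a block that for 280 against 15 mGy was 1629, and 2041 without 70 mGy replicate 1 in addition, and it was 1599 with the replicate number as a block. Leaving out 15 mGy replicate 1 gave 2130 for 280 against 15 mGy, and leaving out 70 mGy replicate 2 gave 1686 for 280 against 70 mGy. An F test over the 4 groups in limma gave 0 probes after adjustment and 1533 before it, and a one-way analysis of variance per probe gave 0 and 1666.

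With 0 adjusted calls at each dose, the overlap of calls between doses was 0. At an unadjusted p under 0.05 and in the same direction, 15 and 70 mGy shared 457 probes, 15 and 280 mGy shared 687, and 70 and 280 mGy shared 955. Simulated unchanged groups, set against 4 simulated control arrays common to all, shared 347, 356 and 349 probes. Independent lists of the observed sizes would share 59.65, 85.6 and 113. The simulated noise was independent between probes, while some real control arrays shared deviating probes. A surplus over the simulation is therefore no measure of what the real shared controls leave unexplained. Across probes, which are not independent replicates, the log2 differences of 15 and 70 mGy correlated with r = 0.628, those of 15 and 280 mGy with r = 0.675 and those of 70 and 280 mGy with r = 0.659. Simulated unchanged groups gave 0.496 to 0.497. The covariances were 0.129, 0.146 and 0.149 against 0.085 in each simulation, which leaves differences of 0.0438, 0.0607 and 0.0644. With the controls split 2 and 2, so that the doses shared none, the mean correlations over the 6 splits were 0.229, 0.281 and 0.283. Single splits ranged from 0.037 to 0.320 for 15 and 70 mGy, from 0.159 to 0.364 for 15 and 280 mGy and from 0.102 to 0.380 for 70 and 280 mGy, and the splits by slide gave means of 0.111, 0.165 and 0.169.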

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

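Of the 44 groups of 4 values examined, 9 held an array set apart from the other 3 of its group by a gap, relative to the range, above Dixon's 95% critical value. A rate of 1 in 20 would give 2.2, which is only a rough guide to chance. Some measures overlap, such as the number and the share of probes well above background, and saturated spots, 0 on every array, can set none apart. The test of spot noise was set before its result was seen. Values for 70 mGy replicate 1 were apart in 4 measures. Its 75th percentile signal was 149.7 against 223 to 231 on the other 3 arrays, the median CV of its repeated probes was 58.9% against 12.4% to 13.7%, the SD of log2 signal over the spots of probes printed 10 times was 0.528 against 0.105 to 0.154, and 246 probes were at least 4-fold above their median over all arrays, against 26 to 58. For 15 mGy replicate 2 the CV was 27.0% against 13.0% to 13.6%, and the SD of the 10-spot probes was 0.289 against 0.108 to 0.127.

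The distance of 70 mGy replicate 1 from the other arrays could come from spot noise on the array or from its RNA. The 2 spots of a probe share any difference of the RNA but not spot noise. Over 3042 probes with 2 spots, the covariance between spots of the deviation from the group was 0.268 on this array, within the range of the other 15 arrays (0.113 to 0.578). The variance not shared by the 2 spots was 0.956, against at most 0.314 elsewhere. These values are in line with spot noise as a source of its distance, without showing that it is the whole. Of the 1182 probes at least 4-fold below their median on this array, 117 were also so low on 15 mGy replicate 2, where independent sets would share 16.2, and noise independent from spot to spot gives no such excess unless some probes are more prone to it, which was not tested. These were the 2 arrays with the highest CV of repeated probes and the only ones in column 4 of slide 1, so an effect of that place stays open. No biological explanation was tested.

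The SD of the 10-spot probes on 280 mGy replicate 2 was 0.105, against 0.138 to 0.139 on the other 3 arrays of that dose. It was low only within its group, since it was also 0.105 on 70 mGy replicate 2 and 0.0988 on control replicate 1. On the same array 350 probes were at least 4-fold above their median over all arrays, against 13 to 19 on the other 3. On 15 mGy replicate 1 this number was 203, against 32 to 46.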

How the results depend on the processing

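The fits within each slide, with position on the slide, of 2 groups with slide as a block and without 70 mGy replicate 1 with slide as a block were chosen after seeing the data. Counts at an adjusted p under 0.05 in limma stayed at 0 for each dose, the trend, the doses against each other and the F test in all alternatives run, apart from the following. With array weights 1 probe passed for the trend, and with only the 2 groups in the fit 6 passed at 280 mGy (2 with slide as a block), against 0 at 15 and 70 mGy. Without 70 mGy replicate 3, 1 probe passed at 70 mGy, 1 between exposed doses and 1 in the F test, so each of these counts ranged from 0 to 1 over the arrays left out. The unadjusted threshold gave 1679, 2210 and 3230 probes at 15, 70 and 280 mGy, 3196 for the trend, 2629 between exposed doses and, by analysis of variance, 1666 among the 4 groups, since it allows chance calls.

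Among unadjusted counts, that at 15 mGy (1679) was 1012 with the filter on all 16 arrays, where fewer probes were tested, 3083 with array weights, 2937 with only the 2 groups and slide as a block and 2762 without 70 mGy replicate 1 and with slide as a block. That at 70 mGy (2210) was 1250 with position as a covariate. Within slide 1, with 2 arrays per group, the counts at 15, 70 and 280 mGy and for the trend were 370, 754, 658 and 727, and within slide 2 that at 15 mGy was 3226. Leaving out 1 array gave 596 (without control replicate 4) to 2746 (control replicate 1) at 15 mGy, with 1039 without control replicate 3, 963 without 15 mGy replicate 2 and 1081 without 15 mGy replicate 3. It gave 1021 (control replicate 4) to 4020 (70 mGy replicate 4) at 70 mGy, with 1463 without 70 mGy replicate 1. It gave 1889 (control replicate 4) to 3962 (control replicate 1) at 280 mGy, and 2011 (control replicate 4) to 3867 (70 mGy replicate 4) for the trend. Over all alternatives, 944 probes for 70 against 15 mGy became 475 to 2357, 1276 for 280 against 15 mGy became 526 to 2765, and 963 for 280 against 70 mGy became 484 to 1842. The cause was not tested. The 4 named probes kept the sign of their difference at 280 mGy in every alternative run, and CUST_22230_PI426552878 was left out by the filter on all 16 arrays. These probes were chosen by that difference, and their irradiated and control samples did not overlap. The kept sign is therefore largely fixed by the choice and is no independent sign of stability.

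With the replicate number of the labels as a block (replicate block), 0 probes passed the adjusted threshold, and 2407, 2614, 3649 and 3561 had an unadjusted p under 0.05 at 15, 70 and 280 mGy and for the trend. The numbers were not taken to pair the samples, since not every pair correlated above 0.1: deviations of the 24 pairs of arrays with the same number correlated from -0.319 to 0.363, 14 above 0.1 (median 0.156, against -0.0516 for different numbers), and 8 of 16 arrays correlated best with one of their own number. That rule does not exclude a pairing, since a real one could leave some pairs below 0.1. Replicates 1 and 2 were on slide 1 and 3 and 4 on slide 2, so number and slide overlap. Gene list tests were not run for lack of gene names, and scan date as a block was not run because it equals slide. With controls split 2 and 2, the overlap of adjusted calls stayed 0. Signal over background limits the rest: 51.3% to 70.9% of probes per array were well above it.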

Other observations

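Some arrays of different doses shared strongly deviating probes. Of the 31512 probes measured on all arrays, 539 were at least 4-fold below their median over the 16 arrays on control replicate 4, 362 on control replicate 3 and 502 on 70 mGy replicate 4. Control replicates 3 and 4 shared 234 of these, control replicate 4 and 70 mGy replicate 4 shared 241, and control replicate 3 and 70 mGy replicate 4 shared 181, where independent sets would share 6.19, 8.59 and 5.77. On the 156 probes low on all 3, the median deviation was -2.55, -2.73 and -2.46 on these arrays and -1.16 on 280 mGy replicate 4, while the other 12 arrays lay between -0.238 and 0.443. All 4 arrays were on slide 2, as were 4 of those 12. Probes at least 4-fold high on 15 mGy replicate 1 (199) and 280 mGy replicate 2 (347), both on slide 1, had 86 in common, with 2.19 expected.

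Some probes were detected in 1 group of a comparison alone, in numbers within the range of other splits of the same arrays. At 280 mGy 60 probes were well above background on all 4 control arrays and on no array of that dose, and 7 the other way round, a total of 67. The other splits of these arrays gave 7 to 655, with a median of 22.5. At 70 mGy the numbers were 110 and 2, a total of 112 against 2 to 335 in other splits (median 19). At 15 mGy they were 3 and 7, a total of 10 against 2 to 242 (median 18.5). The totals at 70 and 280 mGy were thus above the median of the other splits and that at 15 mGy below it. In 309 pairs of probes the identifiers differ only by the suffix AS, whose meaning was not established here. The probe with the suffix was brighter in 178 pairs, with a median log2 difference of 0.719. The log2 differences at 280 mGy correlated with r = 0.0213 over the 52 pairs well above background on all 16 arrays. With 0 adjusted calls at this dose, noise alone could give such a value.

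The fit with slide as a block was planned, but its use as a test of the count at 280 mGy was chosen after that count was seen, as were the test of the correlation between slides, the orders of the arrays within slides and the fit of 2 groups with slide as a block. The other tests in this part were chosen before their results were seen. The excess of probes at an unadjusted p under 0.05 at 280 mGy (3230 against 1582 expected) may come from dose, slide, position on the slide or chance. With slide as a block the count was 3836, but this decides nothing about slide: each slide held 2 arrays of every group, so a slide difference common to the groups cancels in the comparison and the block could only take it out of the residual variance. The outer-minus-inner profile, measured within the 15 and 70 mGy groups, had a covariance with the 280 mGy profile that was -0.363 times that between the 280 mGy profiles of the 2 slides (SD 0.464 over the other assignments of position), where a position effect needs about 1. The 280 mGy profiles of the slides, which share no array, correlated with r = 0.282 against at most 0.124 in other assignments, but 18 assignments are too few for a share under 0.05. The outer arrays at 15 and 70 mGy lay in column 4 of slide 1 and column 1 of slide 2. Those at 280 mGy lay in column 1 of slide 1 and column 4 of slide 2. The ratio thus comes from other places on the slides, and 2 of its arrays had the highest CV of repeated probes. It does not exclude a position effect, which could also make the slides correlate, as position and dose coincide on both. Chance stays open, since 2 of the 35 splits gave as many probes. Radiation dose, position and a slide effect that differs between the groups stay open too.

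The other split with as many probes as the real one at 280 mGy followed the slides (3580), with which scan time and the replicate numbers 1 and 2 against 3 and 4 coincide, so that these cannot be told apart. The highest of the other splits that kept the slides balanced gave 2852, but these 18 splits are too few for a share under 0.05. At 70 mGy 7 of 35 splits gave at least the real 2210, up to 5031. Of these, 5 were unbalanced by slide, and the highest of the other balanced splits gave 2294. At 15 mGy 10 of 35 gave at least 1679, up to 3995, and the highest of the other balanced splits gave 3934. The split by slide gave 3633 probes with the 70 mGy and 1917 with the 15 mGy arrays, while with slide as a block the real grouping gave 2758 and 2311. With all splits counted, chance is therefore not excluded for the counts at the 3 doses. For the trend 11 of 100 orders of all arrays gave at least 3196, up to 5797, which does not exclude chance. Among 100 orders that kept each array on its slide 4 did, up to 4843, a share under 0.05. Of the 99 other orders 3 gave as many. The exact 95% binomial interval of that share, 0.629% to 8.6%, spans 5%, so the orders within slides do not firmly exclude chance either. An effect of position on the slide, which followed the dose, stays open for the trend too. The split that gave 5031 set control replicate 1 with 70 mGy replicates 1, 2 and 3 against the other 4 arrays and called 995 probes after adjustment in the fit of all groups, but 0 with only these 8 arrays in the fit. The split of control replicates 1 and 2 with 70 mGy replicates 2 and 3 called 362 and 326 in these fits. It is named for its many calls and was unbalanced by slide, with 3 of these 4 arrays on slide 1. Whether its calls come from the samples, the slides or single arrays was not tested. The 6 adjusted calls at 280 mGy with only the 2 groups in the fit were reached in 2 of 35 splits. The other, with 455 calls, set slide 1 against slide 2, and no other balanced split gave more than 1 call. With slide as a block the real grouping gave 2 calls. Over all 35 splits chance is not excluded, and the 18 balanced ones are too few for a share under 0.05.

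The profiles of the 3 doses correlated with each other, which the shared control arrays could produce. Measured across slides with no array in common, the correlations were 0.213 for 15 and 70 mGy, 0.191 for 15 and 280 mGy and 0.261 for 70 and 280 mGy. The highest of the other assignments of control and exposed arrays within slides gave 0.118, 0.185 and 0.076. All 3 lay above 0 and above the other assignments, the bound set beforehand, but there were only 18 assignments, and the margin over the highest of them was below their SD for 15 and 280 mGy (0.0063 against 0.122) and for 15 and 70 mGy (0.095 against 0.0955). For 70 and 280 mGy it was 0.184 against 0.0773. The demand applied, that each correlation also exceed 2 SD of the other assignments, was added after the values were seen, and 15 and 280 mGy missed it (0.191 against 0.244). Shared control arrays cannot produce a correlation between profiles with no array in common, though they add to the correlations over all arrays. For the values across slides, a response common to the doses cannot be told apart from chance. An effect of position, with all controls in inner columns on both slides, was not tested for them.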
